A study of Mus musculus with 6 samples.

How the data were processed

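Total RNA of 6 mouse fallopian tube organoid cultures was measured on 6 one-colour (Cy3) Agilent arrays, 1 array for each group, per the labels' protocols with RNeasy extraction and Low Input Quick-Amp labelling. Per the labels, the culture medium held EGF, R-spondin1, Noggin, Y27632, Jagged-1 and CHIR-99021, an inhibitor of GSK3 that activates Wnt signalling. The groups were control (Trp53flox/flox with the vector pLKO.1), Trp53 loss, Pik3ca/Trp53 (Pik3caH1047R with Trp53 loss) before inoculation and tumour-derived, and Apc/Trp53 (Apc580D with Trp53 loss) before inoculation and tumour-derived. The other pair named in the design was not analysed here. All 6 arrays lay on 1 slide and were read in 1 scan. In both pairs the array before inoculation lay in row 1 and the tumour-derived array in row 2, control lay in row 2 and Trp53 loss in row 1, so slide row cannot be separated from these contrasts.

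The deposited scanner files hold background-subtracted intensity per spot from Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers, with no scaling between arrays. Flags for spots well above background, saturated or outlying come with them. The deposited value table holds log2 values of 2047 probes, of which 1459 could be named and 436 were well above background on none of the 6 arrays. Tested on the files, differences between any 2 of its columns equal those of the log2 scanner intensities up to a constant (r of 1, slope of 1). Scaling between arrays would change only that constant, so it was not checked in this way. Its centring and the choice of its probes are not stated. The medians of its columns were 0.03, -0.01, 0.15, -0.05, -0.32 and -0.20 in the order control, Trp53 loss, Pik3ca/Trp53, its tumour-derived culture, Apc/Trp53 and its tumour-derived culture.

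Choices of comparisons, gene lists, the rule for naming genes and the alternatives were made before the data were examined, apart from those called later choices below. Control spots and outlier-flagged spots were left out, and spots of the same probe were averaged. No spot was saturated. Values are log2 of the processed intensity minus the array's 75th percentile. Probes were named by matching their accessions to RefSeq. 34566 of 56605 probes could be named, for 23787 genes, and the other 22039 were not used for genes. A gene's value is the mean over its named probes that are well above background on at least 1 of the 2 arrays compared. Where a probe was dim on 1 array, a lower bound of the fold was computed by raising the dim signal to the lowest level well above background on that array, and the text then gives "at least" that fold. R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, were used.

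There were 5 comparisons of 2 arrays. They were Trp53 loss minus control, Pik3ca/Trp53 and Apc/Trp53 each minus Trp53 loss, and each tumour-derived culture minus its source. With 1 array per group none has a test, and genes were counted at a log2 difference of at least 1. Counts of genes and of list members used signals as measured, without the bounds. A gene counted as 2-fold apart can therefore have a bound under 2-fold. The median difference of each of 29 gene lists (815 genes) was ranked among 10000 random lists of the same size, matched on deciles of mean expression (seed 1). It was said to stand apart at or under the 2.5th or at or above the 97.5th percentile, which describes these arrays and is no test of the groups. On simulated data, 6.5% of 200 unshifted lists of 25 genes fell outside and 99.5% of lists shifted by 0.5 log2 units were found above. The lists cover p53, Wnt, FOXO, Notch, TGF-beta and BMP, YAP and ERK targets, CDK inhibitors, lipid synthesis, glycolysis and hypoxia, proliferation, oxidative stress, ER stress, interferon response, antigen presentation, inflammation, matrix remodelling, EMT and stem cell genes, and markers of secretory, multiciliated, general, squamous and gastrointestinal epithelium, fibroblasts, leukocytes, endothelium, adipose and skeletal muscle, and mesothelium. Adipose and skeletal muscle genes had medians of -0.01, -0.12, -0.01, 1.35 and 0 in the 5 comparisons. The median of every list is in the figure of list medians. 2 further lists, of mammary epithelium and of oviduct transcription factors, were later choices, made after the values were seen.

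2 limma fits (moderated t-test, Benjamini-Hochberg over genes, adjusted p of 0.05) were made. Both used signals as measured, without the bounds, so their folds can rest on dim signals. The paired fit compared both tumour-derived arrays with both arrays before inoculation, with genotype as a block and 1 residual degree of freedom, on genes above background on at least 2 of 4 arrays. The other compared the 3 Trp53-loss cultures before inoculation with the single control, with 2 residual degrees of freedom, on genes above background on at least 1 of 4 arrays. Both were tested on simulated data with 200 changed genes. At the real residual spread the paired fit recovered 0% at 2-fold to 64-fold, and the Trp53 fit 0%, 0%, 49% and 80.5% at 2-fold, 4-fold, 16-fold and 64-fold. With an SD of 0.1, both recovered 100%.

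Genes were named by rule. In each comparison of 2 arrays these were the 8 largest increases and decreases among genes above background on both arrays, and the 3 largest bounds in each direction among genes above background on 1. To these were added up to 4 members of each list that stands apart, and the 4 members with the largest differences of the p53, Wnt, FOXO, secretory and multiciliated lists. In the limma fits the 5 genes with the smallest p and at least 2-fold change were named, since none passed. Clone, predicted and accession names were passed over, as were genes in the first group whose probes differ in sign. The text names up to 4 members of a list. Some genes that the rule names are not reported here. Targeted genes are given on all arrays.

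The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, median scaling, no filter on dim probes, only probes well above background on all 6 arrays, the brightest probe per gene, the values as deposited, a log2 threshold of 1.5, random lists without matching, and for the fits no genotype block, all 6 arrays together, and leaving out single arrays. Normexp used median spot brightness, because the files hold no mean. A later choice was Trp53 loss as the reference of the Pik3ca tumour-derived culture.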

Results

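Total RNA of mouse fallopian tube organoids was measured on 6 one-colour arrays, 1 for each of 6 groups. Fallopian tube organoids are cysts of oviduct epithelium grown in a matrix from primary cells. The reference culture came from Trp53flox/flox mice and carried the control vector pLKO.1. Trp53 encodes the tumour suppressor p53. A second culture had lost Trp53. The other cultures added to this loss either Pik3caH1047R, an activating mutant of the PI3-kinase catalytic subunit, or Apc580D, an allele of the Wnt pathway antagonist Apc. Each of these 2 double-mutant cultures was measured before subcutaneous inoculation and again as organoids grown from the resulting tumour. The histology label of the Pik3ca tumour was adenocarcinoma, and that of the Apc lesion was cyst. The design names 3 such pairs. 2 were available, and the other one was not analysed here. The groups are called control, Trp53 loss, Pik3ca/Trp53 and Apc/Trp53 below, with "tumour-derived" for the 2 later cultures.

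Each array carried 56605 different gene probes. The share of them well above background was 48.71% in control, 48.08% in Trp53 loss, 45.44% in Pik3ca/Trp53, 48.55% in its tumour-derived culture, 49.94% in Apc/Trp53 and 50.95% in its tumour-derived culture. Probes printed in 10 copies differed between copies by a median SD of 0.0389 to 0.0797 log2 units per array. Every group had 1 array, so no difference between 2 arrays has a replicate check or a p-value, and the number of arrays limits the precision of all values below. A gene is called 2-fold higher or lower as a statement about those 2 arrays. The within-array spread above and the median SD between probes of the same gene, 0.128 to 0.212 log2 units over the 5 comparisons, cover technical error only. Of 145 medians (29 gene lists in 5 comparisons), 83 lay outside the central 95% of random lists, where 7.25 would if list members varied independently. Members of a pathway or cell type can vary together, so 7.25 is no expectation for these lists. The comparisons also share arrays, so the 145 medians are not independent.

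The targeted genes were read first, each by a single probe. The Trp53 signal was 0.88 log2 units above the array's 75th percentile in control. It was not well above background in Trp53 loss, in Pik3ca/Trp53 or in tumour-derived Apc/Trp53, where control was at least 44.6-fold, 34.8-fold and 48.2-fold higher. It was well above background in Apc/Trp53 and in tumour-derived Pik3ca/Trp53, at 22.2-fold and 5.72-fold below control. Tumour-derived Pik3ca/Trp53 was therefore at least 6.07-fold above the culture it came from. The Pik3ca signal was 1.55 in control, 0.96 in Trp53 loss, 1.94 in Pik3ca/Trp53, -0.23 in its tumour-derived culture, 0.75 in Apc/Trp53 and 2.10 in its tumour-derived culture. The Apc signal stayed between -4.63 and -3.68, near the background limit, on all 6 arrays. The positions of these probes relative to the altered exons are not given in the sources used here, so the Pik3ca and Apc values are no check of the genotypes.

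**Figure D1:**
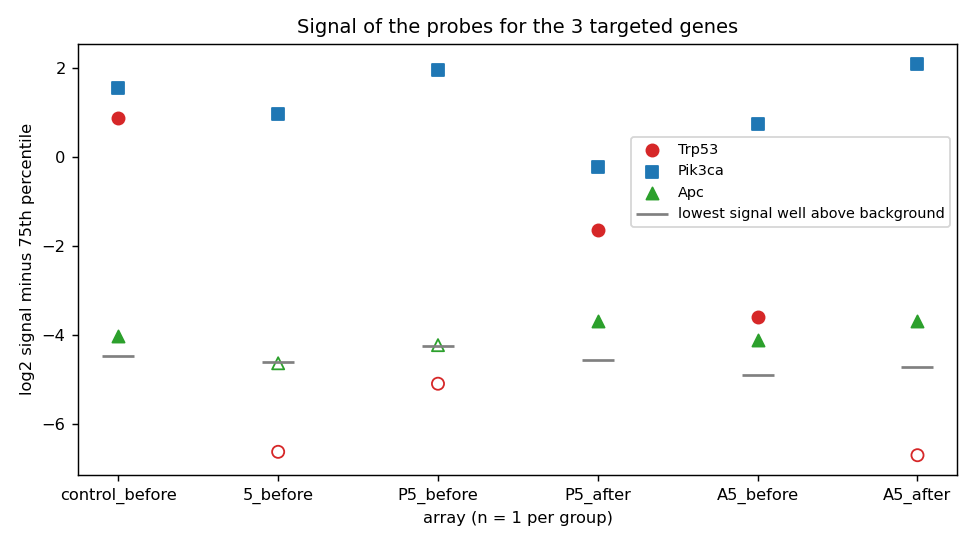
Log2 signal minus the array's 75th percentile (vertical axis) of the single probes for Trp53, Pik3ca and Apc on the 6 arrays (horizontal axis, n = 1 per group). Open symbols mark signals not well above background, and grey bars the lowest signal well above background. Trp53 is at 0.88 in control and at -1.64 in the tumour-derived Pik3ca/Trp53 culture.

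The comparison of Trp53 loss with control asks what losing Trp53 alone does in these organoids. Genes of the p53 pathway and of multiciliated cells were lower after Trp53 loss, and cell cycle genes were slightly higher. Of 38 measured p53 targets, 20 were at least 2-fold lower and 0 were 2-fold higher, with a median log2 difference of -1.05. Cdkn1a, which encodes the cell cycle inhibitor p21, was at least 26-fold lower over 2 probes that differed by an SD of 2.42 log2 units. Phlda3, an inhibitor of AKT, was 15-fold lower, Ddit4l at least 15.3-fold and Eda2r at least 7.03-fold. The markers of multiciliated cells, the cells that carry motile cilia, had a median of -1.49, or -0.92 with dim signals raised to the background limit. Counted without the bounds, 21 of their 34 measured members were 2-fold lower and none was 2-fold higher. Dynlrb2, a dynein light chain, was 10.8-fold lower, Fam183b at least 3.12-fold, Cdhr3 at least 2.58-fold and Dnah6 at least 1.79-fold.

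Over all genes, 841 of 14361 were at least 2-fold higher and 1088 at least 2-fold lower in Trp53 loss than in control. These counts include dim signals. Of these genes, 455 and 654 were above background on both arrays. Among genes above background on 1 of the 2 arrays only, 185 were higher and 260 lower with a bound of at least 2-fold. Among genes above background on both arrays, the largest increases were in Sult1d1, a sulfotransferase (at least 32.7-fold), Elapor1 (at least 15.2-fold), Hsd11b1, which regenerates active glucocorticoid (22.1-fold), Umod, which encodes uromodulin (21.7-fold), the Wnt-responsive receptor Lgr5 (18.1-fold), Gpx3 (16.6-fold), Aebp1 (14.4-fold) and Prl6a1 (13.8-fold). The largest decreases were in Mgmt, a DNA repair methyltransferase (72-fold), Cdkn1a, the protease inhibitor Serpine2 (39.5-fold), Tnfrsf11b, which encodes osteoprotegerin (19-fold), Galnt14 (at least 10.7-fold), Psrc1 (17-fold), Crnde (at least 16.8-fold) and Col8a1 (16.6-fold). Apoc1 (at least 56.2-fold), Inmt (at least 31.7-fold) and the potassium channel gene Kcnj1 (at least 29.1-fold) were above background in Trp53 loss alone of the 2 arrays, and Trp53, Ddit4l and Krtap1-5 (at least 15.2-fold) in control alone.

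Several other lists stood apart from random lists of similar expression. Matrix remodelling genes had a median of -0.83, with 12 of 29 at least 2-fold lower and 3 at least 2-fold higher. Among them, the basement membrane collagens Col4a1 and Col4a2 were 5.2-fold and 4.69-fold lower, the protease Adam8 at least 4.56-fold and Adam12 at least 3.14-fold. Medians were also lower for oxidative stress genes (-0.56; 7 of 30 at least 2-fold lower; Gsta2 5.84-fold lower, Hmox1 2.46-fold), TGF-beta and BMP targets (-0.54; 6 of 22 at least 2-fold lower and 4 at least 2-fold higher; Pmepa1 3.26-fold lower), YAP targets (-0.45; 1 of 24 at least 2-fold lower; Ankrd1 2.37-fold, Ccn1 1.83-fold) and squamous and basal markers (-0.43; Krt13 at least 6.69-fold, Sprr2f 12.7-fold), although 6 of 22 squamous and basal markers were 2-fold higher and 6 at least 2-fold lower. Medians of inflammatory cytokines (-0.32; Cxcl15 2.96-fold, Il1a 2.32-fold) and interferon response genes (-0.24; Oasl1 2.57-fold, Usp18 2.38-fold) were slightly lower. Of the cytokine list 4 of 33 were 2-fold higher and 4 at least 2-fold lower, and of the interferon list 2 of 34 were 2-fold higher and 4 at least 2-fold lower. Endothelial markers (-0.42; Ptprb 3.53-fold lower) lay at the edge of the random range, at percentile 2.41 in 1 draw of random lists and 2.62 in another, so the draw alone decides that call. Proliferation genes had a median of 0.59, although only 2 of 39 reached 2-fold, Cenpa at 2.02-fold and Rrm2, a ribonucleotide reductase subunit, at 2.0-fold. Medians were slightly higher for CDK inhibitors (0.35; 2 of 8 at least 2-fold higher and 1 at least 2-fold lower), glycolysis and hypoxia genes (0.28; 2 of 32 at least 2-fold higher) and cholesterol and fatty acid synthesis genes (0.21; 1 of 31 at least 2-fold higher). In the first 2 of these lists, Cdkn2a, which encodes p16 and p19ARF, was 5.35-fold higher and Ankrd37 3.93-fold.

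The medians of Wnt targets (-0.06), FOXO targets (0.11) and secretory oviduct markers (-0.01) lay within the random range, with single members on both sides. Ascl2 was 3.38-fold higher, Dkk3 3.44-fold lower, the FOXO target Igfbp1 at least 7.04-fold higher, Pdk4 3.35-fold and Irs2 2.77-fold higher, and Bcl2l11 at least 2.82-fold lower. Of the secretory markers, the transcription factor gene Wt1 was at least 20.2-fold higher in Trp53 loss, while Ovgp1, which encodes oviductin, was 5.31-fold lower, Lypd2 2.44-fold and Msx1 2.26-fold. The 15 lists inside the random range had medians between -0.29 and 0.13. Dividing by the median instead of the 75th percentile moved the median of all genes to 0.22 and the counts to 1092 higher and 856 lower. The calls for CDK inhibitors, endothelium and squamous markers were each lost under 1 alternative.

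The next comparison, of Pik3ca/Trp53 with Trp53 loss, asks what the PI3-kinase mutant adds. The single Trp53 loss array is shared by this comparison, the one before and the next, so its own deviations enter all 3, with the opposite sign in the first. Interferon response genes, antigen presentation genes and cell cycle genes were higher in Pik3ca/Trp53, and ERK pathway, YAP and mesenchymal genes were lower. 30 of 35 measured interferon response genes were 2-fold higher and none was 2-fold lower (median 2.49). Isg15, an interferon-induced ubiquitin-like protein, was 16-fold higher, the antiviral genes Ifit1 and Oas2 11.1-fold and 10.6-fold, and Trim30a at least 9.64-fold. 8 of 18 antigen presentation genes were 2-fold higher (median 0.95), including the immunoproteasome subunits Psmb9 (6.91-fold) and Psmb8 (6.58-fold), the peptide transporter Tap1 (4.43-fold) and Cd74 (4.03-fold). The median of leukocyte markers was 0.03, inside the random range, with 4 of 13 at least 2-fold higher and 1 at least 2-fold lower. In Pik3ca/Trp53, 34.04% of their probes were well above background, against 25.53% in Trp53 loss and 27.66% in control.

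Proliferation genes were 2-fold higher in 30 of 39 cases, with none 2-fold lower (median 1.46). Birc5, which encodes survivin, was 5.49-fold higher, the mitotic transcription factor Foxm1 at least 3.61-fold, Melk 4.47-fold and cyclin A2 (Ccna2) 4.38-fold. CDK inhibitors were higher too (median 0.84; Cdkn3 3.28-fold, Cdkn2d 3.01-fold, Cdkn2c 2.42-fold), as were cholesterol and fatty acid synthesis genes (0.35, with 4 of 31 at least 2-fold higher; Mvk 2.62-fold, Srebf1 2.12-fold) and Notch targets (0.47, with 2 of 11 at least 2-fold higher and 1 at least 2-fold lower; Lfng 4.63-fold, Notch1 2.42-fold). Secretory oviduct markers had a median of 0.38. In that list Msx1 was 6.72-fold higher, Wt1 3.44-fold, Ovgp1 2.81-fold and Pwwp3b at least 3.27-fold, whereas Krt7 was 3.26-fold lower.

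Genes induced by ERK signalling had a median of -0.80, with 11 of 24 at least 2-fold lower. The transcription factor gene Etv1 was 25-fold lower, Fosl1 at least 4.85-fold, and the feedback inhibitor genes Spry1 and Spry4 5.77-fold and at least 1.93-fold. YAP targets (median -0.60, 9 of 24 at least 2-fold lower) included Ankrd1, at least 10.8-fold lower, and Crim1, 3.14-fold lower. Of the EMT and mesenchymal genes (median -1.03, or -0.64 with dim signals at the background limit), Tgfb2 was at least 26.8-fold lower, Cdh6 4.92-fold, Zeb2 at least 1.61-fold and Snai1 at least 1.52-fold. TGF-beta and BMP targets (-0.55, with 8 of 22 at least 2-fold lower and 5 at least 2-fold higher; Id4 at least 4.54-fold, Bmp4 4.99-fold), ER stress and amino acid response genes (-0.38; Chac1 3.53-fold, the asparagine synthetase gene Asns 3.17-fold, Trib3 2.96-fold) and inflammatory cytokines (-0.23; Csf2 at least 5.88-fold, Cxcl2 3.01-fold) were lower. FOXO targets, which active PI3-kinase signalling is known to lower, had a median of -0.34. 7 of 25 were 2-fold lower and none was 2-fold higher, with the insulin receptor substrate gene Irs2 at 5.08-fold lower, Klf15 at least 4.85-fold, Igfbp1 at least 6.0-fold and Pdk4 at least 4.26-fold. This rests in part on the shared reference, since Irs2, Igfbp1 and Pdk4 were higher in Trp53 loss than in control. Against control, FOXO targets in Pik3ca/Trp53 had a median of -0.15, at percentile 12.72 and inside the random range. So were Notch targets (-0.13, of opposite sign), secretory markers (0.37), gastrointestinal markers (-0.45) and ER stress genes (-0.12). The FOXO median against Trp53 loss was 0.01 when only probes above background on all 6 arrays were used. Matrix remodelling genes (-0.35; Timp3 14.7-fold, Mmp13 at least 3.16-fold), multiciliated markers (-0.56, or -0.10 with dim signals at the background limit; Cfap43 at least 2.7-fold, Zmynd10 at least 2.4-fold, Ccno at least 3.85-fold, Dynlrb2 at least 3.16-fold), gastrointestinal markers (-0.53, or -0.16 so bounded; Lgals4 2.91-fold) and p53 targets (-0.20, with 2 of 35 at least 2-fold lower and 2 at least 2-fold higher; Gdf15 6.08-fold, Phlda3 2.13-fold) were below the random range. Their sign turned when dim probes were kept. Tap1 and Ckap2, both also among the p53 targets, were 4.43-fold and 2.86-fold higher.

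In all, 1303 of 14237 genes were 2-fold higher and 1216 at least 2-fold lower. Gulo, the last enzyme of vitamin C synthesis, was 141-fold higher, Wfdc18 43.7-fold, Khdc1a 35.6-fold, Cxcl15 24.2-fold, Apol9b 19.9-fold, the transferrin gene Trf 19.7-fold, and Cldn22 19.2-fold. Kap (at least 151-fold), Abat (at least 34.4-fold) and the lysozyme gene Lyz1 (at least 25-fold) were above background in Pik3ca/Trp53 alone of the 2 arrays. Gpx3 was 46.7-fold lower, the apolipoprotein gene Apoe at least 19.1-fold, Scel at least 15.3-fold, Epb41l3 at least 18.4-fold, Cdo1 at least 10.2-fold and Cys1 20.2-fold, beside Tgfb2 and Etv1. Hpcal4 (at least 35-fold), Hsd11b1 (at least 27.8-fold) and Kcnj1 (at least 24.8-fold) were above background in Trp53 loss alone. Gpx3, Hsd11b1 and Kcnj1 were among the genes higher in Trp53 loss than in control, so these reversals rest on the 1 shared array. The median of Wnt targets was 0.03, with Tnfrsf19 6.04-fold and Nkd1 at least 2.53-fold higher, and Myc 3.23-fold and the cyclin D1 gene Ccnd1 2.71-fold lower. The 11 lists inside the random range had medians between -0.63 and 0.32. Pik3ca/Trp53 was the array with the fewest probes above background and the largest spread between copies of a probe. The calls for secretory markers, Notch targets, TGF-beta targets, inflammatory cytokines and EMT genes were also lost under at least 1 alternative.

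The comparison of Apc/Trp53 with Trp53 loss asks what the Apc allele adds. The Wnt target list was higher, with 12 of 27 measured members 2-fold higher and 1 lower (median 0.82). The feedback inhibitor gene Nkd1 was at least 35.6-fold higher, the Wnt antagonist genes Dkk2 and Wif1 22.7-fold and 6.07-fold, and Apcdd1 8.73-fold over 3 probes with an SD of 0.181. ERK pathway output (-0.50, 4 of 25 at least 2-fold lower), YAP targets (-0.50, 7 of 24) and glycolysis and hypoxia genes (-0.46, 6 of 32) were lower. The size of the glycolysis median depends on the shared Trp53 loss array, since against control it was -0.07, at percentile 1.94. Among the members of the 3 lists, Etv1 was 3.3-fold lower, the EGF receptor ligand gene Hbegf 2.73-fold, Dusp6 2.21-fold, Ccn2 4.18-fold, Nt5e 4.08-fold, the prolyl hydroxylase gene Egln3 2.64-fold, carbonic anhydrase 9 (Car9) 2.5-fold and Vegfa 2.13-fold.

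Interferon response genes were modestly higher in Apc/Trp53 (median 0.60, 8 of 34 at least 2-fold higher and 1 at least 2-fold lower), with Oas2 at 3.89-fold, Cxcl10 at 2.88-fold, Iigp1 at 2.86-fold and Isg15 at 2.45-fold. Proliferation genes had a median of 0.39 with no member 2-fold apart (E2f1 1.84-fold, Foxm1 1.77-fold). ER stress genes had a median of 0.26 with 1 of 28 at least 2-fold higher (Sdf2l1 2.85-fold, Manf 1.73-fold). Endothelial markers had a median of 0.95, or 0.44 with dim signals at the background limit. Kdr, a VEGF receptor, was 8.5-fold higher, Cdh5 3.87-fold and Vwf 2.85-fold. Lower medians were found for matrix remodelling genes (-0.38; Mmp13 at least 5.0-fold, Loxl1 at least 5.14-fold, Adamts1 4.1-fold), FOXO targets (-0.24; Pdk4 3.35-fold, Txnip 2.54-fold, Cited2 2.06-fold), inflammatory cytokines (-0.27; Csf2 5.29-fold, Il33 at least 4.05-fold), EMT genes (-0.31; Axl 2.62-fold, the osteopontin gene Spp1 2.58-fold), gastrointestinal markers (-0.41; Krt20 5.93-fold, Muc5ac 3.15-fold), mesothelial markers (-0.83; Upk3b 3.22-fold), fibroblast markers (-0.91, or -0.63 with dim signals at the background limit, over 6 measured genes; Col6a2 at least 14.3-fold, Fbln2 3.52-fold), leukocyte markers (-0.32; Cd68 3.01-fold) and epithelial junction genes (-0.14; Elf3 1.76-fold). Of leukocyte markers 1 of 10 was 2-fold lower, and no junction gene was 2-fold apart. Against control, the medians in Apc/Trp53 of interferon response genes (0.20), mesothelial markers (-0.49) and fibroblast markers (0.06, of opposite sign) were inside the random range, so these 3 calls depend on the shared reference array.

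Wt1, which belongs to both the secretory and the mesothelial list, was at least 27.2-fold lower in Apc/Trp53, while Msx1 was 6.3-fold higher, Lypd2 4.97-fold and Ovgp1 3.16-fold. The secretory list as a whole had a median of -0.03, the multiciliated list 0.20 and the p53 targets -0.02, all inside the random range. In these lists the transcription factor gene Myb was at least 4.3-fold higher, Hydin at least 1.51-fold, Ccdc39 at least 1.23-fold and Cdkn1a at least 1.84-fold, Zmat3 1.67-fold, while Cfap43 was 3.02-fold lower and Pmaip1 1.9-fold. The FOXO target Klf15 was 3.49-fold higher. Counts were 786 genes 2-fold higher and 750 at least 2-fold lower of 14464. The largest increases were in Ecrg4 (55.2-fold), Col8a1 (27.3-fold), the growth factor gene Fgf3 (at least 12.3-fold), Prr18 (at least 15.2-fold), Dkk2, the retinaldehyde dehydrogenase gene Aldh1a1 (21.6-fold), Krt23 (21.3-fold) and Tent5c (20.4-fold), and, above background in Apc/Trp53 alone of the 2 arrays, the serine protease gene Prss29 (at least 140.0-fold), Rnf138rt1 (at least 112-fold) and Nkd1. Among the largest decreases were the lymphotoxin gene Lta (31.9-fold), Mmp23 (15.6-fold), Inmt (11.3-fold), the clusterin gene Clu (10.1-fold), Ppbp (9.82-fold), Csdc2 (9.12-fold) and Elavl4 (at least 4.05-fold, over 2 probes with an SD of 4.18), and, above background in Trp53 loss alone, Cyp2c68 (at least 28.1-fold), Wt1 and Krt26 (at least 17.5-fold). The 12 lists inside the random range had medians between -0.11 and 0.24. The calls for epithelial junctions, EMT genes, fibroblast, leukocyte and gastrointestinal markers were lost under at least 1 alternative.

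**Figure D2:**
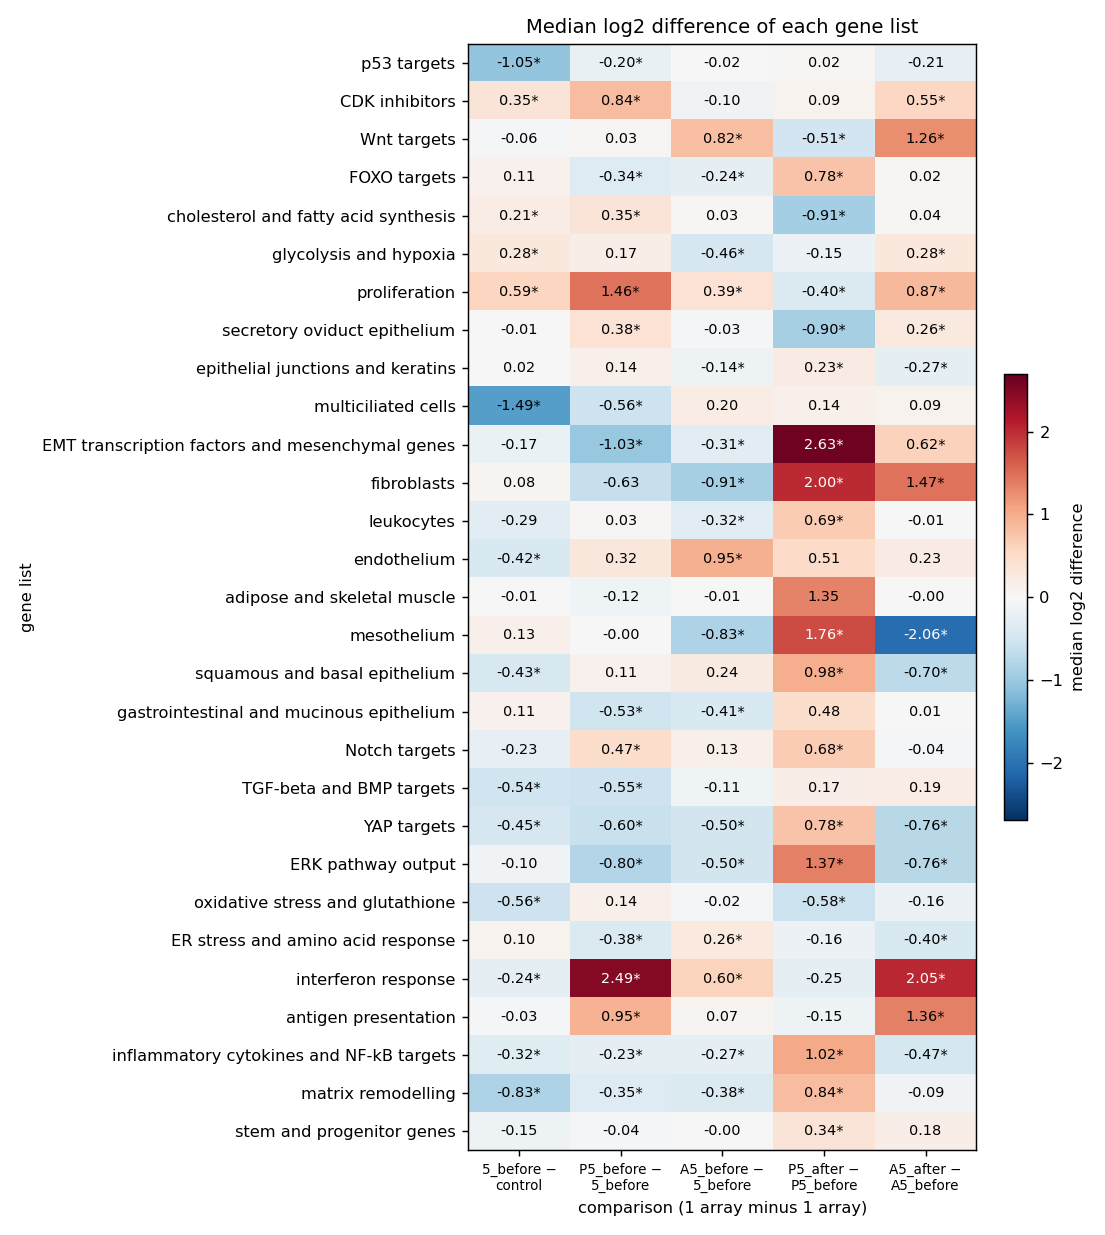
Median log2 difference (colour and number) of the measured members of each of 29 gene lists (vertical axis) in the 5 comparisons of 2 arrays (horizontal axis). An asterisk marks medians outside the central 95% of 10000 random lists of the same size and expression. The interferon list reaches 2.49 in Pik3ca/Trp53 and 2.05 in tumour-derived Apc/Trp53.

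The tumour-derived Pik3ca/Trp53 culture was compared with the culture it came from, to see which genes differ after growth in the animal. Basal keratins, mesenchymal genes, ERK pathway genes and inflammatory genes were higher, and Wnt targets, secretory oviduct markers and cholesterol and fatty acid synthesis genes were lower. 13 of 27 squamous and basal markers were 2-fold higher and 3 lower (median 0.98). The basal keratin genes Krt5, Krt14 and Krt17 were at least 209.6-fold, 237-fold and 169.6-fold higher, and Krt6b at least 16.8-fold. 13 of 20 EMT and mesenchymal genes were 2-fold higher and none 2-fold lower (median 2.63, or 1.75 with dim signals at the background limit), among them the matrix protein gene Sparc (at least 30.8-fold), Snai1 (at least 10.5-fold), Fbln5 (at least 25.5-fold) and Tgfb2 (at least 13.6-fold). ERK pathway output had a median of 1.37, with 13 of 24 at least 2-fold higher and none lower. Etv1 was 38.6-fold higher, Etv5 5.77-fold, Fosl1 at least 3.59-fold and Spry4 at least 2.82-fold.

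Inflammatory cytokines and NF-kB targets (18 of 35 at least 2-fold higher, median 1.02) included the serum amyloid genes Saa1 and Saa2, 263-fold and at least 1168-fold higher, Csf2 (at least 7.86-fold) and Tslp (at least 3.87-fold). Saa1 and Saa2 are close paralogs, so their probes cannot be counted as independent. Matrix remodelling genes (0.84, 14 of 32 at least 2-fold higher) included the collagenase gene Mmp13 (at least 36.7-fold), Mmp3 (at least 7.77-fold), Timp3 (29-fold) and Col17a1 (at least 6.39-fold). FOXO targets (0.78; Fbxo32, a muscle ubiquitin ligase, 39.6-fold, Cited2 6.15-fold, Irs2 5.55-fold, Klf6 4.0-fold), YAP targets (0.78; Ankrd1 at least 25.6-fold, Axl at least 4.17-fold), Notch targets (0.68, with 5 of 13 at least 2-fold higher and 3 at least 2-fold lower; the ligand gene Dll1 at least 52.1-fold, Hey1 43.1-fold, Nrarp at least 6.35-fold) and stem and progenitor genes (0.34, with 4 at least 2-fold higher and 3 at least 2-fold lower of 19; Aldh1a3 33.4-fold, Cd44 at least 11.9-fold) were also higher. The median of epithelial junction genes was slightly higher (0.23; Spint1 1.9-fold, Krt19 1.81-fold), but none was 2-fold apart. Markers of other cell types moved with them. Fibroblast markers had a median of 2.0, or 1.09 with dim signals at the background limit, over 8 measured genes (periostin, Postn, at least 89.9-fold; Fbln2 5.29-fold; Acta2 at least 3.5-fold). Mesothelial markers had a median of 1.76, or 0.89 so bounded (Bnc1 at least 4.43-fold, Rspo1 at least 4.67-fold, Msln 3.68-fold), and leukocyte markers 0.69, or 0.48 so bounded, with 6 of 16 at least 2-fold higher and 3 at least 2-fold lower (S100a9 at least 17-fold, S100a8 27.3-fold, Cd163 at least 3.98-fold). The leukocyte median lay at the edge of the random range, at percentile 97.51. The share of leukocyte probes above background was 34.04% both before inoculation and in the tumour-derived culture. The calls for secretory, fibroblast, mesothelial, leukocyte, stem cell and junction lists were each lost under at least 1 alternative, and the medians of fibroblast and leukocyte markers turned to -0.15 and -0.062 when dim probes were kept.

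Wnt targets had a median of -0.51, with 12 of 27 at least 2-fold lower and 7 at least 2-fold higher. Axin2, a direct target and feedback inhibitor of the pathway, was at least 14.5-fold lower, Lgr5 30.8-fold, Tnfrsf19 at least 17.4-fold and Nkd1 at least 2.47-fold, while Wnt10a was at least 7.8-fold higher. Secretory oviduct markers had a median of -0.90, or -0.32 and inside the random range with probes above background on all 6 arrays. Msx1 was 251-fold lower, Wt1 at least 74-fold, Sox17 6.73-fold and Lypd2 at least 2.12-fold, while Chil1 and Folr1 were 18.9-fold and 7.21-fold higher. Cholesterol and fatty acid synthesis genes (-0.91, 13 of 31 at least 2-fold lower) included Mvd (5.29-fold), Cyp51 (2.95-fold) and Pmvk (2.88-fold). Oxidative stress genes (-0.58) included the glutathione transferase genes Gstm1 (6.19-fold), Gstm2 (7.01-fold) and Gstm3 (6.44-fold), a family whose probes may share targets, and Gpx2 (5.95-fold). Proliferation genes had a median of -0.40, with no member 2-fold apart (Ccna2 1.94-fold lower, Mcm3 1.88-fold). Multiciliated markers (0.14) and p53 targets (0.02) were inside the random range. In the first list Cfap43 was at least 5.08-fold, Ccno at least 6.34-fold and Pifo at least 2.5-fold higher and Gmnc at least 2.25-fold lower. In the second Ddit4l was at least 10.7-fold higher, Rb1 at least 13-fold and Phlda3 7.16-fold.

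This pair differed more than any of the other 4 comparisons, with 2148 genes 2-fold higher and 1537 at least 2-fold lower of 14727. Under median scaling the counts were 1923 higher and 1970 lower. Besides those named, the largest increases were in Pdlim3 (218-fold), the IGF-binding protein gene Igfbp5 (146-fold), Lrrc32 (142-fold), Emid1 (at least 53.9-fold) and Gng11 (102-fold). The transcription factor gene Irx1 (at least 1466-fold), Saa2 and the kappa-casein gene Csn3 (at least 1032-fold) were above background in the tumour-derived culture alone of the 2. The largest decreases were in Msx1, Gulo (180.4-fold), the histidine decarboxylase gene Hdc (at least 21.7-fold), Clca1 (40.04-fold), Gstm7 (39.2-fold), Tmem212 (34.1-fold), Wnt11 (at least 27.8-fold) and Plcxd3 (at least 16.1-fold). The Wnt receptor gene Fzd10 (at least 306-fold), its overlapping opposite-strand gene Fzd10os (at least 285-fold) and Thrsp (at least 135-fold) were above background before inoculation only. The 11 lists inside the random range had medians between -0.25 and 1.35. With Trp53 loss as the reference array, chosen after the data were seen, the median of proliferation genes was 1.08 and that of YAP targets -0.07. The signs of both lists thus turned, and the calls for FOXO targets, secretory markers, ERK pathway output, oxidative stress genes, mesothelial markers, leukocyte markers and stem and progenitor genes were lost.

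The tumour-derived Apc/Trp53 culture was compared with its own source in the same way. Wnt targets, interferon response and antigen presentation genes were higher, and mesothelial, ERK, YAP and squamous genes were lower. 16 of 29 Wnt targets were 2-fold higher and 1 lower (median 1.26), with Nkd1 at 20.7-fold, Dkk3 at least 14.4-fold, Wnt10a at least 4.71-fold and Wif1 at 15.4-fold. 29 of 35 interferon response genes were 2-fold higher and none lower (median 2.05), with Trim30a at least 54.1-fold, Ifi27l2a at 18.9-fold, Ifit1 at 11.7-fold and Ifit3 at 10.02-fold. 12 of 18 antigen presentation genes were 2-fold higher (median 1.36; Psmb8 8.69-fold, Psmb9 6.79-fold, the class II gene H2-Ab1 at least 4.99-fold, Tap2 5.27-fold). The leukocyte list had a median of -0.01, inside the random range, with 2 of 12 at least 2-fold higher and 3 at least 2-fold lower. Proliferation genes had a median of 0.87 with 15 of 39 at least 2-fold higher, among them Ccnb2 (3.0-fold), Mki67, which encodes Ki-67 (2.92-fold), and Kif2c (2.9-fold).

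Mesothelial markers had a median of -2.06, or -0.99 with dim signals at the background limit, over 7 genes (Upk3b at least 5.63-fold lower, mesothelin, Msln, 5.46-fold, complement C3 4.18-fold). ERK pathway output (-0.76, 11 of 24 at least 2-fold lower) included Fosl1 (at least 6.03-fold), Egr1 (3.83-fold) and Epha2 (3.07-fold). YAP targets (-0.76, 10 of 24) included Ankrd1 (at least 5.34-fold), Ccn2 (4.04-fold) and Edn1 (3.81-fold). Squamous and basal markers (-0.70; Krt5 at least 3.27-fold, Krt6b at least 3.32-fold, the transglutaminase gene Tgm1 5.52-fold), inflammatory cytokines (-0.47; Cxcl2 at least 5.72-fold, Il1a at least 3.56-fold, Cxcl17 8.65-fold), ER stress and amino acid response genes (-0.40; Trib3 8.67-fold, Chac1 8.08-fold, Mthfd2 4.82-fold, Asns 4.05-fold) and epithelial junction genes (-0.27; the desmoplakin gene Dsp 2.15-fold, Ocln 1.85-fold; 1 of 26 at least 2-fold lower) were also lower. EMT genes (0.62, with 7 of 20 at least 2-fold higher and 4 at least 2-fold lower; Sparc at least 7.52-fold, Cdh2 at least 2.84-fold), fibroblast markers (1.47, or 0.79 with dim signals at the background limit, over 9 genes; Pi16 at least 4.64-fold, the PDGF receptor gene Pdgfra at least 7.79-fold) and CDK inhibitors (0.55; Cdkn3 2.34-fold, Cdkn2d 2.2-fold) were higher. Secretory markers (0.26; Lypd2 3.71-fold, Msx1 2.49-fold, the progesterone receptor gene Pgr 2.45-fold, Ovgp1 2.19-fold) and glycolysis genes (0.28; Bnip3 2.0-fold, 1 of 32 at least 2-fold higher and 1 at least 2-fold lower) were higher under the 75th percentile scaling, but their medians were -0.07 and -0.05 under median scaling. In the secretory list Chil1 was 5.98-fold and Krt7 2.62-fold lower.

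FOXO targets (0.02), multiciliated markers (0.09) and p53 targets (-0.21) were inside the random range. Irs2 was 3.99-fold and Klf6 3.1-fold lower, Pik3ip1 3.04-fold and Tnfsf10 3.04-fold higher. The multiciliated regulator gene Ccno was at least 8.47-fold lower, Hydin at least 1.64-fold and Ccdc39 at least 1.33-fold. The p53 targets Gdf15 and Phlda3 were 17.6-fold and 4.62-fold lower, and Tap1 was 4.07-fold higher. 1686 genes were 2-fold higher and 1197 at least 2-fold lower of 14889. The largest increases were in Gulo (79.8-fold), Igfbp2 (64-fold), the epoxide hydrolase gene Ephx2 (57.4-fold), Dhrs3 (at least 26.3-fold), Mia (40.6-fold), Prss28 (at least 17.9-fold), Cd83 (36.8-fold) and Smoc2 (34.2-fold), and in the uroplakin gene Upk3a (at least 63.8-fold), Trim30a and Cpsf4l (at least 32.9-fold), which were above background in the tumour-derived culture only. The largest decreases were in the urate oxidase gene Uox (99-fold), Serpinb10 (53.7-fold), Prap1 (51.6-fold), Gdf15 and 4 genes of the alpha-1-antitrypsin family, Serpina1a (17.6-fold), Serpina1c (17.8-fold), Serpina1d (21.8-fold) and Serpina1e (17.5-fold), whose near-identical sequences may share probes. Kcnj1 (at least 69.3-fold), Kcne2 (at least 51.5-fold) and the parvalbumin gene Pvalb (at least 29.6-fold) were above background before inoculation only. Under median scaling the median of all genes was -0.37 and the counts were 1250 higher and 2061 lower. The 13 lists inside the random range had medians between -0.21 and 0.23, and the calls for EMT and fibroblast lists were lost under at least 1 alternative. The median of mesothelial markers turned to 0.22 when dim probes were kept, and that of fibroblast markers to -0.073 with probes above background on all 6 arrays.

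**Figure D3:**
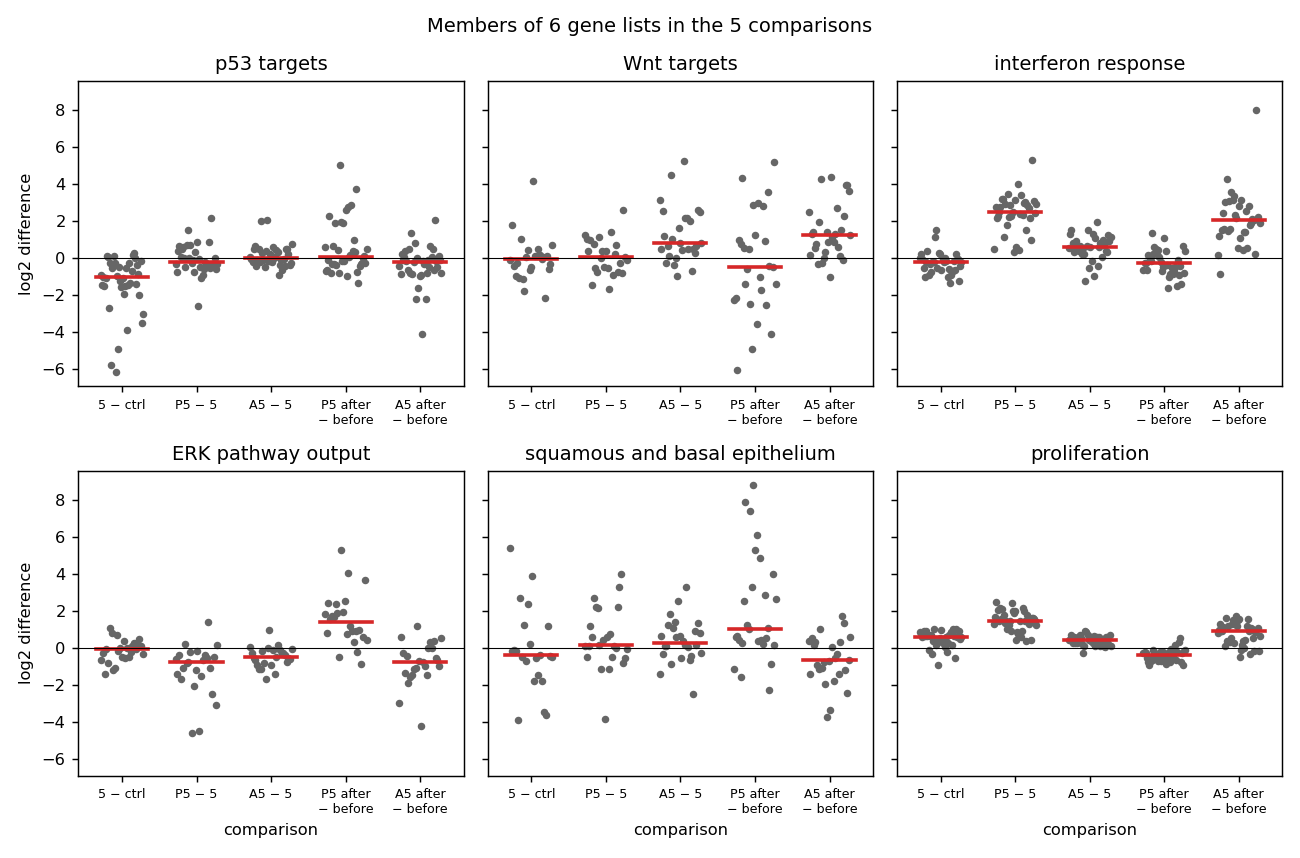
Log2 difference (vertical axis) of every measured member (grey points) of 6 gene lists in the 5 comparisons of 2 arrays (horizontal axis), with red bars at the median; "ctrl" is control, "5" Trp53 loss, "P5" Pik3ca/Trp53 and "A5" Apc/Trp53. Wnt targets have medians of -0.51 and 1.26 in the Pik3ca and Apc tumour pairs, and ERK pathway genes 1.37 and -0.76.

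The 2 tumour comparisons share no array. Across 13933 genes measured in both, their log2 differences had a Pearson r of -0.074 and a Spearman rho of -0.069; genes are not independent replicates. 321 genes were 2-fold higher in both pairs, where 131.9 would be under independence, and 154 were 2-fold lower in both, against 105.8. Opposite directions were more common, with 375 genes higher in the Pik3ca pair and lower in the Apc pair, against 117.9, and 319 the other way, against 118.4. Every combination of directions exceeded independence, so the genes shared in 1 direction are no sign of a shared change. A limma fit of tumour-derived against before with genotype as a block, on 4 arrays and 1 residual degree of freedom, gave 0 of 14219 genes past an adjusted p of 0.05. 544 genes had an unadjusted p under 0.05. Simulated changes of up to 64-fold in 200 genes were not recovered at this residual spread. Larger numbers of changed genes were not simulated. The 0 genes that passed therefore do not show that none changed. The smallest p values among genes moved at least 2-fold belonged to the endothelin receptor gene Ednra (85.7-fold higher in both pairs on average, adjusted p = 0.999), Pdgfrl (26.2-fold), Cntn1 (36.6-fold) and Carmn (38.3-fold), which were higher, and Angptl8 (16.0-fold), which was lower. These folds are without the bounds for dim signals. Adjusted over the list alone, 2 of 29 Wnt targets and 1 of 5 fibroblast markers were higher, and no member of the other 27 lists passed.

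Control was the reference of the design, and the 5 other arrays can each be set against it. These values share the control array, so its own deviations enter all 5. In the order Trp53 loss, Pik3ca/Trp53, tumour-derived Pik3ca/Trp53, Apc/Trp53 and tumour-derived Apc/Trp53, p53 targets had medians of -1.05, -1.08, -0.93, -0.98 and -1.12. Multiciliated markers had medians of -1.49, -2.12, -1.50, -1.52 and -1.54, and proliferation genes 0.59, 2.14, 1.66, 0.92 and 1.82. Wnt targets were at -0.06, -0.10, -0.50, 0.88 and 2.47. A limma fit of the 3 Trp53-loss cultures before inoculation against the single control array gave 0 of 15026 genes past an adjusted p of 0.05, with 1275 at an unadjusted p under 0.05. It assumes that the control would vary as the 3 others do, takes its spread from 3 different genotypes, and carries the deviations of the 1 control array in every gene. Of simulated changes, 0% were recovered at 4-fold and 49% at 16-fold. Folds from this fit are without the bounds for dim signals. Under quantile normalization 76 genes passed, 2 higher and 74 lower. The smallest p values were those of Sult1d1 (45.2-fold higher), Irak3 (17.5-fold lower), Prr23a3 (35.5-fold lower), Cacnb2 (31.2-fold lower) and Ppp1r3g (22.7-fold higher), each with an adjusted p of 0.168. Under the same limits, adjusted over the list alone, 11 of 38 p53 targets and 15 of 37 multiciliated markers were lower at an adjusted p under 0.05. Of the other lists, 2 EMT genes were lower, 1 gastrointestinal marker was higher, and CDK inhibitors and stem cell genes each had 1 member in either direction.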

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

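All tests in this part were chosen after the results were seen. The values below were picked out because the Pik3ca and Apc tumour-derived cultures moved in opposite directions from their sources, with 1 array on each side. The differences between the 2 pairs were not tested.

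Median log2 differences in the Pik3ca pair and the Apc pair were -0.51 and 1.26 for Wnt targets, -0.40 and 0.87 for proliferation genes, -0.90 and 0.26 for secretory oviduct markers, and 0.23 and -0.27 for epithelial junction genes. They were 1.76 and -2.06 for mesothelial markers, which become 0.89 and -0.99 with dim signals raised to the background limit (and 0.22 in the Apc pair without the filter on dim probes), 0.98 and -0.70 for squamous and basal markers, 0.78 and -0.76 for YAP targets, 1.37 and -0.76 for ERK pathway output, and 1.02 and -0.47 for inflammatory cytokines. Single genes, with dim signals raised to the background limit, were Gulo (-7.50 and 6.32), Msx1 (-7.97 and 1.32), Igfbp2 (-4.19 and 6.0), Hdc (-4.44 and 1.19), the interferon-induced gene Trim30a (-1.39 and 5.76), the basal keratin gene Krt14 (7.89 and -1.18), Prap1 (1.76 and -5.69), Serpina1a (1.15 and -4.14), Serpina1d (1.06 and -4.44) and Serpina1e (1.16 and -4.13). The 3 Serpina1 genes are near-identical paralogs and may share signal, which was not tested, so they count as 1 observation at most.

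An effect of the row of the slide would move both pairs the same way, because both sources lie in row 1 and both tumour-derived arrays in row 2. The 9 lists that stood apart in opposite directions are the pattern itself, so their number decides nothing about the row of the slide. A row effect shared by both pairs cannot by itself give opposite directions, as in Wnt targets (-0.51 and 1.26). Across 13933 genes not picked for direction, Pearson r was -0.074, which argues against such an effect as the main source. A smaller row effect stays open. The 321 genes 2-fold higher in both pairs exceed the 131.9 under independence, but so do genes in opposite directions (375 against 117.9 and 319 against 118.4). The excess of genes higher in both pairs is therefore no sign of a shared shift. A deviating array in the Pik3ca pair could also turn lists, since its source had the fewest probes above background and its tumour-derived array correlated least with the other 5 (r 0.887 to 0.927), although r was also low for the tumour-derived Apc array (0.887 to 0.954). With Trp53 loss as the reference instead, 4 of the 9 lists still stood apart against the Apc pair (Wnt targets -0.77, epithelial junctions 0.30, squamous markers 2.47, inflammatory cytokines 0.42), and proliferation genes were at 1.08. For the other 5 lists, a deviating array and an effect of the Pik3ca mutant before inoculation cannot be told apart with 1 array per group, and for all 9 a mixed or mislabelled tumour-derived Pik3ca culture (Trp53 at 17.5% of control, casein genes), genotype and histology (adenocarcinoma and cyst) stay open and untested.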

How the results depend on the processing

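With Trp53 loss as the reference of the Pik3ca tumour pair, chosen after the data were seen, and with all other alternatives planned, 532 list medians under an alternative kept their direction and stayed apart from random lists, 53 kept their direction only and 14 turned. For named genes, 2707 values kept their side of 2-fold, 17 came past it and 131 fell under it. Of genes at least 2-fold apart before any alternative, 0 turned. For named genes under 2-fold the direction was not compared. Of the counts of 2-fold genes under an alternative, 41 stayed within 1.5 times and 41 moved further. Of the limma counts, 18 stayed at 0 and 1 rose from 0.

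Counts (higher and lower, in the order Trp53 loss, Pik3ca/Trp53, Apc/Trp53, Pik3ca tumour pair, Apc tumour pair) moved to 299 and 371, 616 and 460, 249 and 244, 1189 and 730, and 662 and 522 with normexp and quantile normalization. Quantile normalization alone gave 960 and 992, 1301 and 1157, 808 and 712, 2103 and 1565, and 1535 and 1407. The fall therefore came with the normexp step. Its offset and its use of median spot brightness were not tested apart. With probes well above background on all 6 arrays they were 348 and 492, 776 and 596, 320 and 320, 998 and 982, and 681 and 754, and from the deposited values 273 and 336, 175 and 281, 158 and 223, 349 and 221, and 272 and 211, both on fewer genes. At a log2 threshold of 1.5 they were 509 and 622, 765 and 663, 434 and 419, 908 lower in the Pik3ca tumour pair, and 1082 and 649. Without the filter on dim probes 1229 genes were lower in Apc/Trp53, for a cause not tested. Under median scaling 2061 genes were lower in the tumour-derived Apc culture. Its median signal was 32.24 against 23.32 in its source, and its 75th percentile 563.1 against 513.6. Scaling by the median therefore lowers all differences of this pair by the same amount. The limma fit of tumour pairs gave 0 genes under every alternative run (24 to 933 at an unadjusted p under 0.05). The limma fit of Trp53 loss gave 76 under quantile normalization (smallest adjusted p 0.0465, from 0.101 to 0.443 under the others) and 0 under the others (228 to 1536 unadjusted), also 0 to 0 leaving out each Trp53-loss array, with the lone control assumed to vary like the others.

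Medians turned as follows, and apart from median scaling the cause was not tested. Without the filter on dim probes, Pik3ca/Trp53 had 0.001 for p53 targets, 0.13 for multiciliated markers, 0.25 for gastrointestinal markers and 0.15 for matrix remodelling, the Pik3ca tumour pair had -0.15 for fibroblasts and -0.062 for leukocytes, and the Apc tumour pair had 0.22 for mesothelium. With probes above background on all 6 arrays, Pik3ca/Trp53 had 0.006 for FOXO targets and 0.13 for multiciliated markers, and the Apc tumour pair -0.073 for fibroblasts. With Trp53 loss as the reference, the Pik3ca tumour pair had 1.08 for proliferation and -0.073 for YAP targets. Median scaling, which shifts all differences of a pair by the same amount, gave -0.054 for glycolysis and -0.073 for secretory markers in the Apc tumour pair.

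Median scaling moved the median of all genes to 0.22 in Trp53 loss, -0.21 in the Pik3ca and -0.37 in the Apc tumour pair. Without the filter it was 0.23 in Pik3ca/Trp53, -0.17 in Apc/Trp53, -0.27 in the Pik3ca and 0.14 in the Apc tumour pair, and from the deposited values -0.20 in Trp53 loss, -0.34 in Pik3ca/Trp53, 0.65 in the Pik3ca and 0.20 in the Apc tumour pair. The share of 2-fold genes that were higher moved from 43.6% to 56.1% in Trp53 loss and from 58.5% to 37.8% in the Apc tumour pair under median scaling, from 58.5% to 47.5% in the latter with probes above background on all 6 arrays, and from 51.7% to 38.4% in Pik3ca/Trp53 from the deposited values. Slide or scan as a block was not run, since there is 1 of each. Leaving out 1 pair leaves the other pair's comparison, a value with no test. Lists were not run from the deposited values, whose probes were selected. From 45.44% to 50.95% of probes per array are well above background, and for genes of the other probes only bounds or no values can be given.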

Other observations

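All tests in this part, the mammary list and the list of oviduct transcription factors were chosen after the results were seen.

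The tumour-derived Pik3ca/Trp53 culture expressed genes known from mammary epithelium, picked out after their values were seen. Csn3, which encodes kappa-casein, was at least 1032-fold higher than in its source, with both of its probes above background in this culture and in none of the other 5 arrays. Csn1s1, another casein gene, was at least 223-fold higher, the lactalbumin gene Lalba 84.7-fold, the transcription factor genes Irx1, Sox10, Elf5 and Gata3 at least 1466-fold, at least 240.0-fold, 11.3-fold and 4.37-fold, the oxytocin receptor gene Oxtr at least 89.4-fold, and the basal keratin genes Krt5 and Krt14 at least 209.6-fold and 237-fold. Csn2, Wap and Lao1, also mammary genes, were not above background in this culture. The oviduct factor genes Msx1 (251-fold) and Sox17 (6.73-fold) were lower, while Pax8 differed by -0.90 and Esr1 by -0.90 on the log2 scale. Its Pik3ca signal, at -0.23, was the lowest of the 6 arrays, against 1.94 in its source.

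Trp53 signal also returned in this culture, to 17.5% of control, where its source was not above background. A candidate explanation is cells with intact Trp53 in the culture. Of the p53 targets at least 4-fold lower after Trp53 loss, 2 (Eda2r and Zfp365) are not above background on either array of this pair. The 5 that the pair measures had a median log2 difference of 1.90 from the source. In the Apc pair these targets had -0.82. That pair is no neutral comparison, since its source had Trp53 signal above background (4.51% of control) and its tumour-derived culture had not. The same targets had 0.61 in Apc/Trp53 minus Trp53 loss. The whole p53 list had 0.02 in the Pik3ca pair, at the 76.9 percentile of random lists, and stayed at -0.93 against control. Cells with intact Trp53 as an explanation thus stay open. Noise or cross-hybridisation at single probes was weighed with the mammary list, of which 13 of 15 measured genes were at least 2-fold higher, 9 of the 15 from below background, but the 18 genes were listed for the pattern and cannot decide it (7 are above background in control, 2 are in another list). Dilution of organoid cells by other cells would lower oviduct factors as far as other lower genes. 5 of these factors had a median of -0.90 against -1.74 for all lower genes, with Emx2 at -0.27 and Foxl2 at -0.11 on probes that hardly vary. The lower genes were chosen for being at least 2-fold lower in this same pair, and the 5 factors were not. Their medians therefore decide nothing about dilution. Dilution, a mislabelled or mixed sample and a change of cell identity cannot be told apart here.

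Interferon response genes had medians against control of -0.24 in Trp53 loss, 2.12 in Pik3ca/Trp53, 1.65 in its tumour-derived culture, 0.20 in Apc/Trp53 and 2.31 in its tumour-derived culture, so their level followed neither genotype nor growth in the animal alone. Scaling does not account for it, since the median of Pik3ca/Trp53 minus Trp53 loss was 1.97 to 2.57 over the 4 scalings. Leukocytes in the culture may bring such genes. A first test on the share of leukocyte probes above background (34.04% in Pik3ca/Trp53, 29.79% in tumour-derived Apc/Trp53, 27.66% in control) decided nothing, and the median of leukocyte markers chosen next, 0.03 in Pik3ca/Trp53 minus Trp53 loss and -0.01 in the Apc pair, decides nothing either, since over the 2 comparisons 6 marker values were at least 2-fold higher (Lyz1 at least 25-fold) and 4 at least 2-fold lower. Culture passage, day or line stays open, because the labels give passage or day for 0 arrays, and a response to culture or vector cannot be told apart from these.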
